A study of Mus musculus with 15 samples.

How the data were processed

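Expression was measured with 15 Affymetrix mouse 430A arrays in uterine segments of female mice, with 6 µg of total RNA per array. Each array was taken as a separate mouse. The deposited values are MAS5 signals, an intensity on a linear scale, per the submitters' processing notes; the MAS5 version is not given in the sources used here. The authors had scaled each array globally, and the 2% trimmed mean of the deposited intensity was 500 on 9 arrays and 250 on 6. The table held 22690 probe sets and no missing values. Of these, 20393 carried 1 gene symbol, 691 several and 1606 none, for 12394 different symbols, and 64 were controls, which were left out. The 3' to 5' signal ratio ran from 0.732 to 0.918 for Gapdh and from 1 to 1.211 for Actb.

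Each array was rescaled to a 2% trimmed mean of 500, and values were transformed as log2(signal + 50). Probe sets with a mean rescaled signal of at least 100 were kept (15586), and each gene was represented by the probe set of highest mean. Probe sets without a single symbol stayed as features of their own, which gave 10477 features, 9244 of them with a symbol. A model of 5 group means was fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes(trend = TRUE), with 10 residual and 4.5 prior degrees of freedom. The threshold was a Benjamini-Hochberg adjusted p of 0.05 within a comparison. Group means and SDs are of rescaled signals, and changes are on the log2 scale with the moderated standard error (SE). Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

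The 11 comparisons were hyperplasia against wild type (both genotypes and each), invasive carcinoma against hyperplasia (both genotypes and each), invasive carcinoma against wild type, Mlh1 loss on the Pten+/- background (each lesion and both), and the interaction of Mlh1 loss and lesion. Comparisons that use the same arrays are not independent.

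Gene lists were written before the data were examined, from general knowledge, and used only as markers in bulk tissue. The 32 lists held 603 entries, of which 531 were on the array and 456 were measured. Lists with at least 3 measured genes (31) were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The ciliated oviduct list had too few measured genes. Members were counted by the adjusted p over all genes and by one adjusted over the list alone.

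The genes named were chosen by a rule also fixed beforehand. They were the genes of largest change in each direction among those past the threshold, with a symbol and with every array on its group's side of the midpoint of the group means. Up to 10 per direction were taken for hyperplasia against wild type, for invasive carcinoma against hyperplasia over both genotypes and for Mlh1 loss in hyperplasia, 5 for invasive carcinoma against wild type and 3 elsewhere. In comparisons over both genotypes or lesions, both also had to have the same sign. Where none passed, the 5 genes of smallest p were taken. For each list past its test, up to 4 members of smallest p were added. Akr1cl, Akr1c18, Star and Nr5a1 in Pten+/- invasive carcinoma, the named genes near Mlh1 and the unnamed probe set were chosen after their values were seen. Of the 508 entries, 139 had another probe set for the gene, and in 10 of these one had the opposite sign.

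The procedure was tested on simulated data with 200 changed genes of 10477, at the group sizes of each comparison. A log2 change of 1 was recovered in 84% of genes for hyperplasia over both genotypes, 73% and 74% for each genotype, 89% for invasive carcinoma against hyperplasia, 59% for each genotype, 68% for invasive carcinoma against wild type, 74%, 30% and 90% for Mlh1 loss in hyperplasia, in invasive carcinoma and in both, and 22% for the interaction. False calls numbered 5 to 17 per comparison. Genes were simulated as independent, with the same spread in every group. The real arrays vary together across genes and unequally between groups, so these figures are not their error rate. The number of arrays limits the precision, and groups of 2 give an SD of little weight.

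Where a group mean lies under the offset of 50, the offset limits the log2 change, which holds for the named genes S100a8, Cxcl2, Cyp11a1, Hsd3b1, Agr2, BC023105, Mvk and Serpina3n. Alternatives changed one choice at a time. They were an offset of 10 or 200, no filter or a filter at 300, quantile normalization, values as deposited, eBayes without the trend, every probe set by itself, only the groups compared, array weights, the smooth muscle list mean as a covariate, each array left out in turn, and the number in the label as a replicate block. The scaling target as a covariate, only the arrays scaled to 500 or to 250, and leaving out a pair of invasive arrays were added after seeing the data. Per-gene alternatives were run for the named genes past the threshold and for the uncalled genes that the text names. This set was narrowed after a first run over all named entries had been seen, in which 66 values changed sign. Uncalled members were chosen for the text after their values were seen.

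The numbers 1 to 4 recur in labels of Pten+/- hyperplasia and of the invasive groups. The correlation of deviations from the group means between arrays that share a number was 0.114, 0.031, 0.011 and -0.022. The last values pair Pten+/- hyperplasia with Pten+/-;Mlh1-/- invasive arrays, which differ in genotype and so are different mice. For the Pten+/- invasive arrays the correlations cannot decide, since the deviations of a lone pair mirror each other and are not independent. The mice were treated as unpaired, which for the Pten+/- arrays is an assumption. Fold changes of both hyperplasia groups were also compared with separate wild-type arrays, a check added after seeing the data. Regrouping of the arrays compared (up to 100 splits, all 35 where there were fewer) was counted with the same model. Genes within 10 Mb of Mlh1 or Pten were tested against 100000 random sets of the same size from 9232 genes with a position. Mlh1 and Pten expression was not examined by name because no probe set carried either as its single symbol.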

Results

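Gene expression was measured in uterine tissue of female mice aged 16 to 32 weeks, with 1 array per label. The 15 arrays fell into 5 groups. These were wild type (n = 3, arrays 15, 30 and 42), Pten+/- with hyperplasia (n = 4, arrays 1 to 4), Pten+/-;Mlh1-/- with hyperplasia (n = 4, arrays 5 to 8), Pten+/- with invasive carcinoma (n = 2, arrays 1 and 2) and Pten+/-;Mlh1-/- with invasive carcinoma (n = 2, arrays 3 and 4). The labels give the non-invasive lesion only as CAH, without spelling it out, and it was read as a hyperplasia and is called so here. Pten is a phosphatase that opposes PI3-kinase signalling, and Mlh1 is a DNA mismatch repair protein. The wild-type labels number the mouse, whereas the lesion labels number the lesion. Each label was taken as a separate mouse, and only under that assumption do p-values measure the spread between mice. The number of arrays limits the precision of every value. No probe set carried Mlh1 or Pten as its single symbol in the annotation used, so the targeted genes were not analysed by name. Probe sets without a single symbol stayed in the tests, and whether any of them belongs to Mlh1 or Pten was not determined.

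The arrays differed in more than their group. The authors' signals had been scaled to a trimmed mean of 500 on 9 arrays and of 250 on 6. The 6 were all 4 invasive arrays and arrays 5 and 6 of Pten+/-;Mlh1-/- hyperplasia. On the first principal component (25.6% of variance) wild-type array 30 lay at -43.1, and the Pten+/- invasive arrays lay at 33.8 and 34.2. Wild-type array 30 had the lowest mean correlation with the other arrays (r = 0.883 across genes, which are not independent replicates). The Pten+/-;Mlh1-/- invasive arrays 3 and 4 were the closest pair within any group, with an SD of log2 differences of 0.207, against 0.608 to 0.742 between wild-type arrays. Their values were not identical, and they were counted as 2 mice because their labels differ. Nothing else in the data shows that they are separate mice, and if they are not, p-values of the comparisons that use them are too small.

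Hyperplasia was first compared with wild type over both genotypes. Neutrophil-associated genes were among the largest increases. S100a8 and S100a9, calcium-binding proteins abundant in neutrophils, rose by 3.66 (SE 0.45, adjusted p = 0.003) and 3.36 (SE 0.39, adjusted p = 0.0023) on the log2 scale. The mean S100a8 signal was 48.5 ± 50.4 (SD, n = 3) in wild type, 1119 ± 653 (SD, n = 4) in Pten+/- hyperplasia and 1438 ± 900.2 (SD, n = 4) in Pten+/-;Mlh1-/- hyperplasia. The wild-type mean of S100a8 lies under the offset of 50, so the offset sets the size of its log2 change against wild type (2.422 to 4.625 over the alternatives). The chemokines Cxcl5 and Cxcl2, which attract neutrophils, rose by 2.97 (SE 0.44) and 1.60 (SE 0.30), the latter also from a mean under the offset (38.6). Of the 11 measured genes of the neutrophil list, 4 were higher over all genes (6 when adjusted over the list alone), among them the cytokine Il1b at 1.57 and the receptor Csf3r at 1.40. The list rose with a median of 0.77 (camera adjusted p = 2e-07, but adjusted p = 0.089 with an estimated correlation).

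**Figure D1:**
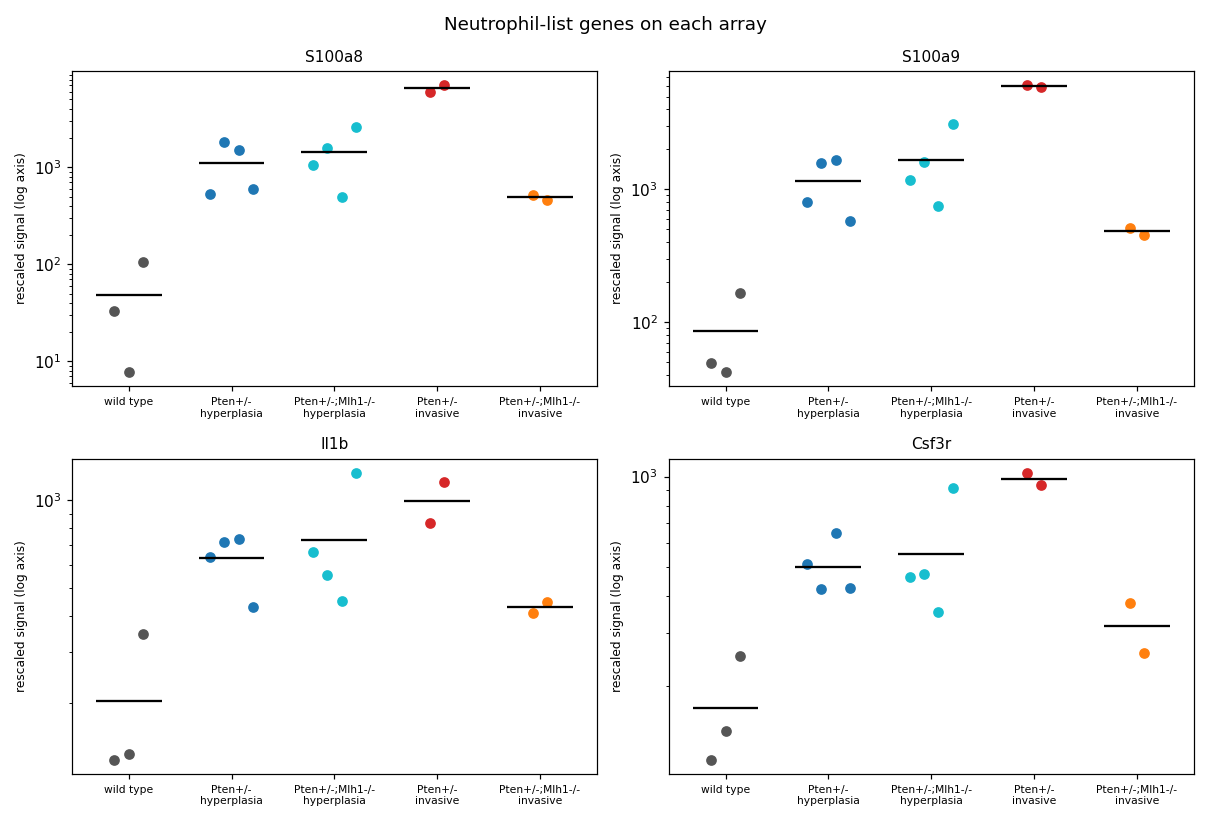
Rescaled signal (arbitrary intensity units, log axis) of S100a8, S100a9, Il1b and Csf3r on each of the 15 arrays (points), by group, with a line at each group's mean signal. The S100a9 mean was 86 in wild type, 1155 and 1661 in the hyperplasia groups, 5994 in Pten+/- invasive carcinoma and 482 in Pten+/-;Mlh1-/- invasive carcinoma.

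Other genes that rose in hyperplasia were Thrsp, a regulator of lipid synthesis, at 1.83, the chemokine Cxcl14 at 1.503, the potassium channel subunit Kcne3 at 1.46 and the RNA exosome subunit Exosc9 at 1.16. Cldn4, a tight junction protein of epithelia, rose by 1.19 (SE 0.25, adjusted p = 0.041). Several matrix and muscle genes fell. Ogn, a small matrix proteoglycan, fell by 1.03 (SE 0.16, adjusted p = 0.01) from 4708 ± 857 (SD, n = 3) in wild type to 2121 ± 419.9 and 2446 ± 287.3 (SD, n = 4 each). The matrix gene Col6a2 changed by -0.93, the myosin light chain Myl9 by -0.84, the creatine kinase Ckb by -1.25, the BMP antagonist Chrdl2 by -1.13 and the mast cell tryptase Tpsab1 by -0.90. Msrb2 (-1.29), Ampd3 (-1.25), Cryz (-1.17), Ccdc71l (-0.95), Rab2b (-0.79) and Gas1 (-0.77) fell as well. An unnamed probe set had the smallest adjusted p, 1.2e-05, and a change of 3.47.

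Fixed lists of muscle and metabolism genes also shifted in hyperplasia as groups. The smooth muscle list had a median of -0.65, with 1 of 16 members lower over all genes and 13 when adjusted over the list alone. Its camera adjusted p was 2e-08, and adjusted p = 0.54 with an estimated correlation. Myh11 and Smtn did not pass over all genes (log2 changes of -1.10 and -0.88). The sterol and fatty acid synthesis list had a median of 0.39, with 0 of 22 members past the threshold in limma over all genes and 9 higher when adjusted over the list alone. Its values included Fdps at 0.96 and Dhcr7 at 0.83 (camera adjusted p = 1.6e-06, adjusted p = 0.4 with an estimated correlation). The proliferation list had a median of 0.48, and 28 of its 30 members were above 0, with Tpx2 at 0.75 and Ube2c at 0.94. None of the 30 passed in limma by either adjustment (camera adjusted p = 2.4e-06, adjusted p = 0.54 with an estimated correlation). In the proliferation list the wild-type arrays themselves ran from -0.46 to 0.72 around their mean, and in the smooth muscle list from -0.56 to 0.46. Wild-type array 42, at 0.72 in the proliferation list, lay above every hyperplasia array (0.09 to 0.65). The rise of that list is therefore only against wild-type arrays 15 and 30. In the smooth muscle list array 42, at -0.56, lay within the range of the hyperplasia arrays (-1.05 to -0.22).

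Camera called 7 more lists. Medians were 0.46 for macrophage genes (C1qc at 0.91, Msr1 at 0.44), 0.28 for epithelium and 0.21 for glycolysis and hypoxia genes (Pkm at 0.59, Car9 at 1.10). They were -0.24 for ribosomal proteins (Rps15 at -0.42, Rps6 at -0.73), -0.19 for oxidative phosphorylation (Sdhb at -0.42, Ndufb8 at -0.49), -0.28 for endometrial stroma and -0.65 for skeletal muscle genes (Tnni2 at -1.35). Their camera adjusted p-values ran from 3e-05 to 0.035, and all 7 were lost with an estimated correlation (adjusted p = 0.54 to 0.85). In these lists 2 stroma genes, Ogn and Col6a2, and 1 epithelial gene, Cldn4, passed over all genes.

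**Figure D2:**
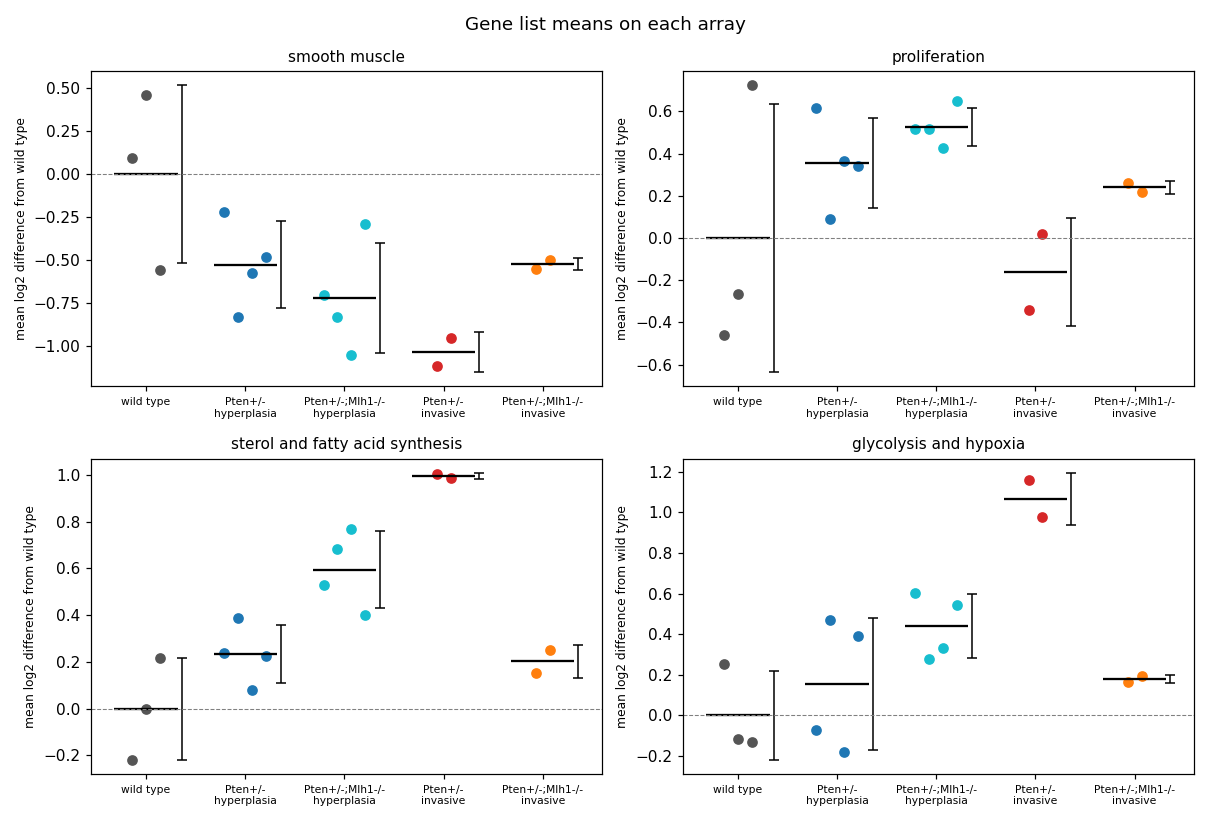
Mean over a list's genes of the log2 difference from the wild-type mean (y axis, log2 units), for each array (points) in 5 groups, with a line at the group mean and a bar of 1 SD. The smooth muscle mean of the wild-type arrays spans -0.56 to 0.46, and the sterol list lies at 1.005 and 0.987 on the Pten+/- invasive arrays.

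In limma, 68 of 10477 genes passed an adjusted p of 0.05 in hyperplasia of both genotypes against wild type, 42 higher and 26 lower. The count depended on single arrays. It was 8, 12 or 715 without wild-type array 15, 30 or 42, 45 or 40 without Pten+/- array 2 or 4, and 44 without Pten+/-;Mlh1-/- array 5. With the scaling target as a covariate 34 genes passed, and within the 9 arrays scaled to 500 the count was 1. It was 7 with array weights and 1 with the smooth muscle list mean as a covariate. With that covariate S100a8 stood at 3.37 (SE 0.615, adjusted p = 0.19), S100a9 at 3.19 (SE 0.539, adjusted p = 0.13), Cxcl5 at 2.23 (SE 0.536), Ogn at -0.95 (SE 0.213) and Myl9 at -0.46 (SE 0.147).

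Each hyperplasia group was also compared with wild type by itself. In Pten+/- mice 7 genes passed (6 higher, 1 lower). S100a8 rose by 3.50 (SE 0.51), S100a9 by 3.14 (SE 0.44) and the kinase Cdk18 by 1.45 (SE 0.24), and Ogn fell by 1.14 (SE 0.18). In Pten+/-;Mlh1-/- mice 78 genes passed (48 higher, 30 lower). Acod1, which makes itaconate in activated myeloid cells, rose by 4.06 (SE 0.60), the chitinase-like protein Chil1 by 4.00 (SE 0.60), Cldn4 by 1.92 (SE 0.28) and the sterol synthesis enzyme Fdps by 1.41 (SE 0.24). Ngfr, a neurotrophin receptor, fell by 2.93 (SE 0.58), Hsd11b2, which inactivates glucocorticoids, by 2.42 (SE 0.52), and the matrix protein Smoc1 changed by -2.17 (SE 0.46).

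Of the neutrophil list, 2 of 11 members were higher in Pten+/- hyperplasia (5 when adjusted over the list alone) and 4 of 11 in Pten+/-;Mlh1-/- hyperplasia (6 when adjusted over the list alone). The list medians were 0.56 and 1.07, with adjusted p = 0.15 and 0.088 with an estimated correlation. Of the endometrial stroma list, 1 of 20 members was lower in Pten+/- and 4 in Pten+/-;Mlh1-/- hyperplasia, the latter including Col1a2 at -1.27 and Col6a3 at -1.56 (1 and 8 when adjusted over the list alone, adjusted p = 0.79 and 0.34 with an estimated correlation). Camera called 9 lists in Pten+/- and 12 in Pten+/-;Mlh1-/- hyperplasia. The sterol list had medians of 0.27 and 0.54, with 0 and 1 of 22 higher (0 and 12 when adjusted over the list alone), and the smooth muscle list had medians of -0.60 and -0.73, with 0 of 16 lower in limma (2 and 12 when adjusted over the list alone). Every call was lost with an estimated correlation (adjusted p = 0.15 to 0.79 and 0.088 to 0.61).

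The fold changes of both genotypes correlated across genes at r = 0.749, against 0.569 in simulations with no effect and shared simulated controls. Their covariance was 0.108, against a simulated 0.035, and 76.4% of genes had the same sign (69.3% simulated). The simulation gave every group the same spread, but the real wild-type arrays varied more. Their SDs of log2 differences were 0.608 to 0.742, against 0.313 to 0.581 within the hyperplasia groups. The simulated values may therefore be too low. All 6 genes higher in Pten+/- hyperplasia were among the 48 higher in Pten+/-;Mlh1-/- hyperplasia (0.03 for independent lists). The lists share their wild-type arrays and are not independent, and an overlap without effect was not simulated. With 1 wild-type array for one genotype and the other 2 for the other, the correlation was 0.071 to 0.302 over the 6 assignments, the covariance 0.014 to 0.062 and the share of the same sign 49.2% to 58.4%. A lone control lowers a correlation by its own noise but not the covariance, which was below 0.108 in all 6. The 0.108 includes noise of the shared controls (0.035 in the simulation), so some fall would come even with a real excess. Part of the excess over the simulation may still come from the shared controls.

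The Pten+/- count was 2, 3 or 404 without wild-type array 15, 30 or 42 and 2, 11 or 3 without Pten+/- array 2, 3 or 4. The Pten+/-;Mlh1-/- count was 23, 18 or 529 without those wild-type arrays, 32, 37, 46 or 51 without array 5, 6, 7 or 8, and 4 with the scaling target as a covariate. Within the arrays scaled to 500, the counts were 1 and 3, and with the smooth muscle list mean as a covariate 1 each. They were 0 and 20 with only the groups compared, 2 and 29 with array weights and 1 and 70 with an offset of 200.

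Invasive carcinoma was compared with hyperplasia to find what changes with invasion. In Pten+/- mice, steroid synthesis genes were among the largest increases. Cyp11a1, which converts cholesterol to pregnenolone, rose by 4.50 (SE 0.43, adjusted p = 0.00031), from 4.7 ± 1.37 (SD, n = 4) to 1633 ± 1616 (SD, n = 2). Hsd3b1, which makes progesterone from pregnenolone, rose by 4.77 (SE 0.47, adjusted p = 0.00031), with signals of 879 and 4277 on the invasive arrays. Cyp11a1 signals on all other arrays were at most 7.32, far under the offset of 50, and Hsd3b1 averaged 24.95 in Pten+/- hyperplasia. The offset therefore sets the size of both log2 changes here and in the other comparisons (2.807 to 6.332 and 3.291 to 5.91 over the alternatives). Inha, the inhibin alpha subunit, rose by 1.84, while Star, a cholesterol carrier, did not pass (0.56, adjusted p = 0.085). Of the 6 measured ovary-list genes 3 were higher over all genes and 5 when adjusted over the list alone (median 1.45, camera adjusted p = 1.5e-05, adjusted p = 0.12 with an estimated correlation). Guca2b, the gut peptide uroguanylin, rose by 5.48 (SE 0.59, adjusted p = 0.00042).

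**Figure D3:**
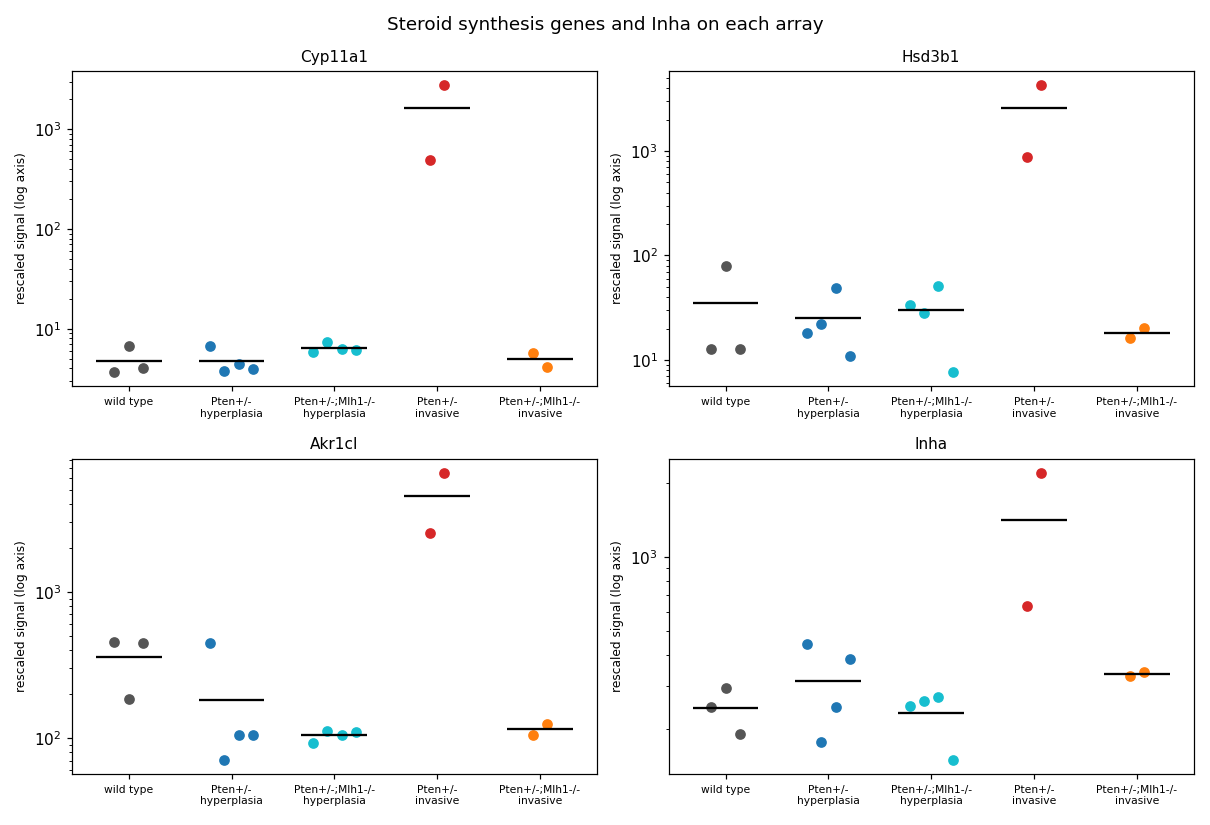
Rescaled signal (arbitrary intensity units, log axis) of Cyp11a1, Hsd3b1, Akr1cl and Inha on each of the 15 arrays (points), by group, with a line at each group's mean signal. Cyp11a1 reads 490 and 2775 on the Pten+/- invasive arrays and at most 7.32 on the other arrays.

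Glucose and sterol metabolism genes rose in Pten+/- invasive carcinoma as well. The glucose transporter Slc2a1 rose by 1.44 (SE 0.21), the lactate transporter Slc16a3 by 1.73 (SE 0.38), the hypoxia-induced peptide Adm by 1.58 (SE 0.34) and the glycolytic enzyme Tpi1 by 0.97 (SE 0.22). Of 20 glycolysis and hypoxia genes, 9 were higher (15 when adjusted over the list alone), with a median of 0.92 (camera adjusted p = 1.4e-08, adjusted p = 0.12 with an estimated correlation). The sterol enzymes Msmo1, Fdps, Fdft1 and Mvd rose by 2.64, 1.89, 1.41 and 1.03, although 1 of 2 other probe sets of Fdft1 had the opposite sign. Of 22 sterol and fatty acid genes, 8 were higher (12 when adjusted over the list alone), with a median of 0.69 (camera adjusted p = 2.8e-08, adjusted p = 0.12 with an estimated correlation).

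Neutrophil genes were higher again in Pten+/- invasive carcinoma, with 5 of 11 past the threshold (7 when adjusted over the list alone). S100a9 rose by 2.45 (SE 0.50), Ngp by 1.97 (SE 0.28), Mmp8 by 1.70 (SE 0.21) and Clec4d by 1.67 (SE 0.30), and the list median was 1.13 (adjusted p = 0.12 with an estimated correlation). Early-response genes rose, with Dusp1 at 1.91, Ier3 at 2.00, Zfp36 at 0.79 and Dnajb1 at 0.61, 4 of 18 in all (6 higher and 1 lower when adjusted over the list alone, median 0.52, adjusted p = 0.26 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose by 1.15 and was the 1 of 20 p53-list genes that passed (1 when adjusted over the list alone, median 0.38, adjusted p = 0.44 with an estimated correlation). Ndufv1, Uqcrc1, Atp5a1 and Cyc1 were the 4 of 27 oxidative phosphorylation genes that rose, by 0.57 to 0.77 (6 when adjusted over the list alone, median 0.27, adjusted p = 0.53 with an estimated correlation). With the values as deposited, without a common scale, the median of all genes lay at -0.87 and Tpi1, Zfp36, Dnajb1, Ndufv1, Uqcrc1, Atp5a1, Cyc1 and Star turned negative. For Atp5a1, 1 of 2 other probe sets had the opposite sign.

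Genes that fell in Pten+/- invasive carcinoma included Malat1, collagens and Mki67. The nuclear noncoding RNA Malat1 fell by 3.59 (SE 0.73, adjusted p = 0.0096) from 3136 ± 1227 (SD, n = 4) to 364 ± 465.5 (SD, n = 2). Resf1 fell by 2.73 and the skeletal muscle actin Acta1 by 2.50. The collagens Col1a1 and Col6a3 fell by 2.07 and 1.68, 2 of 20 stroma genes (8 when adjusted over the list alone, median -0.68, adjusted p = 0.47 with an estimated correlation). The smooth muscle coactivator Myocd fell by 0.80, 1 of 16 in its list (4 when adjusted over the list alone, median -0.46, adjusted p = 0.63 with an estimated correlation). The proliferation antigen Mki67 fell by 2.13 (SE 0.35), 1 of 30 in its list (1 when adjusted over the list alone, median -0.47, adjusted p = 0.64 with an estimated correlation). The repair genes Rfc1 and Msh3 fell by 0.94 and 0.63, 2 of 16 (3 when adjusted over the list alone, median -0.44, adjusted p = 0.63 with an estimated correlation). The epithelium list had a median of 0.62 with 0 of 27 past the threshold in limma by either adjustment (adjusted p = 0.63 with an estimated correlation).

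In all, 888 genes passed in Pten+/- invasive carcinoma against Pten+/- hyperplasia in limma, 331 higher and 557 lower. Without Pten+/- invasive array 1 or 2 the counts were 145 and 389, each leaving a lone invasive array assumed to vary like the other groups, and 522 without hyperplasia array 3. All Pten+/- hyperplasia arrays had the target 500 and both invasive arrays 250, so no value could be had within a target. With the target as a covariate, which uses the split of Pten+/-;Mlh1-/- hyperplasia, 80 genes passed, Cyp11a1, Hsd3b1, Guca2b and Msmo1 among them. Others lost their call with wider errors. Slc2a1 stood at 1.40 (SE 0.323, against 1.44 and 0.205 without the covariate), Mki67 at -1.87 (SE 0.541, against -2.13 and 0.345), S100a9 at 2.62 (SE 0.793, against 2.45 and 0.499) and Col1a1 at -1.37 (SE 0.682, against -2.07 and 0.457).

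In Pten+/-;Mlh1-/- mice 0 genes passed in limma for invasive carcinoma against hyperplasia, with 586 at an unadjusted p under 0.05 (524 by chance) and a smallest adjusted p of 0.21. The 5 genes of smallest p were Cd99 (-1.56, SE 0.28), Map3k11 (-1.24, SE 0.23), Tpsab1 (1.03, SE 0.19), Myocd (0.89, SE 0.17) and 4932438H23Rik (1.05, SE 0.21). The sterol list had a median of -0.38, with 0 of 22 lower over all genes and 4 when adjusted over the list alone, and with Mvk at -1.35 and Idi1 at -1.26 (camera adjusted p = 6.1e-06, adjusted p = 0.62 with an estimated correlation). Camera also called proliferation (median -0.30, Mki67 at -0.66), glycolysis and hypoxia (-0.18, Slc2a1 at -0.53), early response (-0.21, Nr4a1 at -0.58) and endothelium (-0.21, Egfl7 at -0.55). These 4 calls were lost as well (adjusted p = 0.64 to 0.88 with an estimated correlation). Within the arrays scaled to 250, 2 genes passed. With only the groups compared 3 passed, and with array weights 32 (16 higher, 16 lower).

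The difference between genotypes in the change with invasion was tested by an interaction, and 273 genes passed (161 higher, 112 lower). The genes of largest interaction with every array on its side were Smim10l1 (2.02, SE 0.50), the exosome cofactor Mphosph6 (-1.87, SE 0.34), the ephrin receptor Epha2 (-1.46, SE 0.27) and the galectin Lgals3 (-1.36, SE 0.33). Msmo1 and Fdps had interactions of -3.99 (SE 0.51, adjusted p = 0.0053) and -2.83 (SE 0.39, adjusted p = 0.0053), so their change with invasion was lower in Pten+/-;Mlh1-/- than in Pten+/- mice. Slc2a1 had an interaction of -1.97, Dusp1 of -2.27, Cldn4 of -1.91, S100a9 of -3.95 and S100a8 of -3.91, and Myocd one of 1.69. Of the sterol list 7 of 22 were lower (15 when adjusted over the list alone, adjusted p = 0.068 with an estimated correlation), of glycolysis and hypoxia 3 of 20 (12 when adjusted over the list alone, adjusted p = 0.068 with an estimated correlation) and of neutrophil genes 5 of 11 (7 when adjusted over the list alone, adjusted p = 0.068 with an estimated correlation). Among stroma genes Col1a1 reached 2.49 (adjusted p = 0.056).

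The other 8 lists called in the interaction were early response (median -0.78, 3 of 18 lower, 4 when adjusted over the list alone), ovary (-0.96, 2 of 6 lower), epithelium (-0.72, 1 of 27 lower), smooth muscle (0.63, 1 of 16 higher), p53 targets (-0.45), oxidative phosphorylation (-0.34), stroma (0.68) and skeletal muscle (1.09). Their adjusted p was 0.14 to 0.6 with an estimated correlation.

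The interaction count fell when any single invasive array was left out, each such fit leaving a lone array assumed to vary like the other groups. Without hyperplasia array 1, 3, 4, 5, 7 or 8 it was 175, 137, 163, 159, 123 or 141. With the scaling target as a covariate 238 passed. The fold changes with invasion, which shared no arrays between genotypes, correlated across genes at r = -0.073, with the same sign in 48.8% of genes. Of the 331 genes higher in Pten+/- mice, 119 were above 0 in Pten+/-;Mlh1-/- mice.

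Over both genotypes, 74 genes differed between invasive carcinoma and hyperplasia (26 higher, 48 lower). Cd33, a lectin of myeloid cells, rose by 0.68 (SE 0.14), and the acyltransferase Agpat5 and Rai1 fell by 1.10 (SE 0.23) and 0.67 (SE 0.14). They were the only 3 genes past the threshold in which every array lay on its group's side and both genotypes had the same sign. The sterol enzyme Mvd rose by 0.59 and the neutrophil genes Mmp8 and Ngp by 0.93 and 1.16, and Mki67 fell by 1.39. With the values as deposited, without a common scale, Mvd stood at -0.05, but the median of all genes lay at -0.65. Cyp11a1 and Hsd3b1 (2.23 and 2.28) rested on the Pten+/- arrays, and without them they stood at -0.04 and -0.20.

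Camera called 8 lists in this comparison, and all were lost with an estimated correlation. Of neutrophil genes 2 of 11 were higher (4 when adjusted over the list alone, median 0.48, adjusted p = 0.27 with an estimated correlation) and of ovary genes 2 of 6 (5 when adjusted over the list alone, median 0.96, adjusted p = 0.27 with an estimated correlation), namely Cyp11a1 and Hsd3b1, while Inha did not pass (1.15, adjusted p = 0.076). Of proliferation genes 1 of 30 was lower (1 when adjusted over the list alone, median -0.38, adjusted p = 0.73 with an estimated correlation), namely Mki67, while Top2a did not pass (-0.99, adjusted p = 0.15). Medians were 0.11 for sterol (1 of 22 higher), 0.30 for glycolysis and hypoxia, -0.25 for mismatch repair, 0.31 for epithelium and -0.30 for stroma (adjusted p = 0.73 to 0.93 with an estimated correlation). Without the Pten+/- invasive arrays, the sterol, glycolysis, epithelium, stroma and neutrophil medians changed sign and 0 genes passed in limma. Without the Pten+/-;Mlh1-/- invasive arrays 705 passed. The count was 41, 49, 21, 31 or 15 without hyperplasia array 1, 2, 3, 6 or 7. It also fell when any single invasive array was left out, each such fit leaving a lone array assumed to vary like the other groups. It was 0 with the scaling target as a covariate.

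Against wild type, invasive carcinoma of both genotypes differed in 724 genes, 368 higher and 356 lower. Chil1 rose by 5.24 (SE 0.60, adjusted p = 0.0009) from 70.8 ± 17.3 (SD, n = 3) to 5826 ± 174 (SD, n = 2) in Pten+/- and 3466 ± 61.6 (SD, n = 2) in Pten+/-;Mlh1-/- mice. Sprr2d, a cornified envelope protein induced by estrogen in uterus, rose by 4.68 (SE 0.79), S100a8 by 4.37 (SE 0.51), S100a9 by 3.83 (SE 0.44) and Guca2b by 3.24 (SE 0.52). Ngfr fell by 2.43, Hsd11b2 by 2.25, BC023105 by 2.02, the disulfide isomerase Agr2 by 1.93 and Col6a3 by 1.90. Of the neutrophil list 8 of 11 were higher by either adjustment (8 when adjusted over the list alone, median 1.42), and its camera call held with an estimated correlation (adjusted p = 0.039). Of the 110 list calls in the 11 comparisons, no other one held.

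Sterol and glycolysis genes were higher in 8 of 22 and 6 of 20 members (13 and 9 when adjusted over the list alone, medians 0.65 and 0.61), and macrophage genes in 2 of 17 (11 when adjusted over the list alone, median 0.69). Stroma and smooth muscle genes were lower in 7 of 20 and 4 of 16 (9 and 12 when adjusted over the list alone, medians -0.46 and -0.78), with Ogn at -1.07, Myh11 at -1.62 and Cnn1 at -1.54. Epithelium (2 of 27 higher, Cldn4 at 1.15 and Cldn7 at 1.10), ovary (3 of 6 higher, with list means of 1.393 and 2.915 on the Pten+/- and 0.352 and -0.174 on the Pten+/-;Mlh1-/- arrays), skeletal muscle (1 of 4 lower, Acta1 at -2.15) and ribosomal proteins (0 of 18 in limma) were called too. The 9 lists other than neutrophil were lost with an estimated correlation (adjusted p = 0.35 to 0.7). Nsdhl, Ldha, Slc2a1, Msr1 and Fcgr1, which rose by 0.68 to 0.84, turned negative with the values as deposited. There the median of all genes lay at -0.841, since the targets differ, so these signs follow the scaling.

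Without wild-type array 30 or 42 the count against wild type was 275 or 1162. It also fell when any single invasive array was left out, each such fit leaving a lone array assumed to vary like the other groups. All wild-type arrays had the target 500 and all invasive arrays 250, and 1 gene passed with the target as a covariate. There Chil1 stood at 4.23 (SE 0.966), S100a8 at 4.20 (SE 0.869) and S100a9 at 4.00 (SE 0.754), each with an adjusted p of 0.17. With the smooth muscle list mean as a covariate 22 passed, and with array weights 284. Without the Pten+/- invasive arrays 11 passed, and without the Pten+/-;Mlh1-/- invasive arrays 1485.

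Loss of Mlh1 on the Pten+/- background was tested within each lesion. In hyperplasia 1 gene passed in limma, with 680 at an unadjusted p under 0.05 (524 by chance). Igk, an immunoglobulin kappa gene, fell by 3.77 (SE 0.51, adjusted p = 0.031) from 1984 ± 1376 (SD, n = 4) in Pten+/- to 112 ± 151 (SD, n = 4) in Pten+/-;Mlh1-/- mice. Jchain, which joins secreted immunoglobulins, was at -2.05 (adjusted p = 0.067). Of 7 measured B and plasma cell genes 0 were lower over all genes and 4 when adjusted over the list alone, with Cd79a at -0.85 (median -0.82, camera adjusted p = 6.2e-07, adjusted p = 0.31 with an estimated correlation). Against wild type the same list had a median of 0.63 in Pten+/- hyperplasia (camera adjusted p = 0.021, adjusted p = 0.73 with an estimated correlation) and of -0.14 in Pten+/-;Mlh1-/- hyperplasia (camera adjusted p = 0.22).

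Camera called 9 further lists for Mlh1 loss in hyperplasia, with no member past the threshold over all genes in limma and adjusted p = 0.31 to 0.61 with an estimated correlation. The sterol list had a median of 0.30 (Fdps at 0.89), glycolysis and hypoxia 0.26 (Slc2a1 at 0.48), epithelium 0.43 (Cldn4 at 1.47), proliferation 0.18 (Cdc20 at 0.45), interferon response 0.17 (Bst2 at 0.79) and FOXO targets 0.07 (Foxo3 at 0.78). Stroma had a median of -0.35 (Col1a1 at -1.34), MHC class II -0.42 (Ciita at -0.48) and eosinophil and mast cell genes -0.44 (Mcpt4 at -1.05). When adjusted over the list alone, 1 sterol gene and 1 epithelial gene were higher and 2 eosinophil and mast cell genes lower. The count was 0 without Pten+/- array 1, 3 or 4 or Pten+/-;Mlh1-/- array 5 or 7, and 11, 7 or 6 without array 2, 6 or 8. It was also 0 with an offset of 10 and without the filter. With only the groups compared the 1 gene that passed was Guca2b, and within the arrays scaled to 500 it was Cldn4, both higher (2.936 and 1.732), and Igk did not pass in either. The count was 0 with the scaling target as a covariate, where Igk stood at -3.05 (SE 0.559, adjusted p = 0.25, against -3.77 and 0.513 without it). Over all alternatives the change of Igk lay between -4.486 and -2.69, past the threshold in 11 of 21.

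In invasive carcinoma 743 genes differed with Mlh1 loss, 426 higher and 317 lower. Malat1, Resf1 and the kinase Taok1 were higher by 3.66 (SE 0.84), 3.07 (SE 0.35) and 2.52 (SE 0.33) in Pten+/-;Mlh1-/- mice. Hsd3b1, the protease inhibitor Serpina3n and the aldo-keto reductase Akr1cl were lower, at -4.88 (SE 0.55), -4.75 (SE 1.08) and -4.64 (SE 0.56). The genes high in Pten+/- invasive carcinoma were lower here, with Msmo1 at -3.08, Slc2a1 at -1.49, Cdkn1a at -1.47, Zfp36 at -1.21, S100a9 at -3.51 and Cyp11a1 at -4.49, while Mki67 and Myocd were higher at 1.49 and 1.21. Both comparisons used the same Pten+/- invasive arrays and are not independent of each other.

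Of the lists, neutrophil genes were lower in 6 of 11 (7 when adjusted over the list alone), sterol in 7 of 22 (11), glycolysis and hypoxia in 5 of 20 (10) and ovary in 3 of 6 (4), with medians of -1.51, -0.64, -0.84 and -1.30 (adjusted p = 0.16 for each with an estimated correlation). The other 7 lists called were early response (-0.76), p53 targets (-0.31), oxidative phosphorylation (-0.25), macrophage (-0.51), proliferation (0.34), ribosomal proteins (0.25, Rps24 at 0.81) and smooth muscle (0.50), with adjusted p = 0.18 to 0.73 with an estimated correlation. All 4 arrays had the target 250, and with those arrays and the other 2 of that target 1154 genes passed. The count fell when any single invasive array was left out, each such fit leaving a lone array assumed to vary like the other groups.

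Over both lesions, 291 genes differed with Mlh1 loss (151 higher, 140 lower). The immunoglobulin gene Igkv6-14 fell by 1.31 (SE 0.28), the zinc finger gene Maz by 0.81 (SE 0.16) and the phosphate transporter Slc20a2 by 0.79 (SE 0.12). Srebf2, which activates sterol synthesis genes, fell by 0.57, Msmo1 by 1.09 and Mvk by 0.93, 3 of 22 sterol genes (3 when adjusted over the list alone, median -0.15, adjusted p = 0.81 with an estimated correlation). S100a8 and S100a9 fell by 1.64 and 1.53, among 4 of 11 neutrophil genes (6 when adjusted over the list alone, median -0.58, adjusted p = 0.37 with an estimated correlation). The falls of Msmo1, Mvk, S100a8 and S100a9 came from invasive carcinoma (-3.08, -2.11, -3.60 and -3.51), where the interactions passed (-3.99, -2.36, -3.91 and -3.95), and in hyperplasia the sterol list had a median of 0.30 with Mlh1 loss. Cyp11a1 and Hsd3b1 fell by 2.22 and 2.39, likewise from the invasive arrays (-4.49 and -4.88), 2 of 6 ovary genes (4 when adjusted over the list alone, median -0.82, adjusted p = 0.37 with an estimated correlation).

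The early response list had a median of -0.35 with Zfp36 past the threshold (-0.66). Glycolysis and hypoxia (-0.24), B and plasma cell (-0.55), macrophage (-0.30), endothelium (-0.22), proliferation (0.26), mismatch repair (0.18) and ribosomal proteins (0.14) had no member past the threshold over all genes in limma. When adjusted over the list alone, 4 early response, 2 glycolysis and 4 B and plasma cell genes were lower and 2 mismatch repair genes higher. These 8 calls were lost with an estimated correlation (adjusted p = 0.65 to 0.81). The count over both lesions fell when any single invasive array was left out, each such fit leaving a lone array assumed to vary like the other groups. It was 154, 192, 152, 155, 166 or 154 without hyperplasia array 1, 2, 4, 5, 6 or 7, and 36 with the scaling target as a covariate.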

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

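The tests of a batch and of degraded RNA below, and that of less epithelium on a wild-type array, were chosen after the result was seen, except the batch test over all genes.

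Single arrays that stood apart from the other 3 of their hyperplasia group were sought with Dixon's test in 150 groups of values. It found 8, where 7.5 would come by chance at about 1 in 20. In Pten+/- hyperplasia they were the estrogen list on array 3 (-0.081, others 0.406 to 0.485), the 3' to 5' Gapdh ratio on array 1 (0.902, others 0.789 to 0.807) and Tpsab1 on array 4 (135.2, others 87.19 to 95.29). In Pten+/-;Mlh1-/- hyperplasia they were the uterine gland list on array 7 (-0.193, others -0.748 to -0.724), the squamous epithelium list on array 5 (0.9, others 0.397 to 0.451), Chil1 on array 5 (4670, others 1190 to 1524), Igk on array 8 (336.4, others 17.23 to 58.38) and Malat1 on array 8 (1084, others 2664 to 2782).

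Changes with invasion that differ between the genotypes are listed as the interaction, with the Pten+/- and the Pten+/-;Mlh1-/- change in brackets. They are Smim10l1 2.021 (-1.42, 0.601), Mphosph6 -1.869 (1.125, -0.744), Epha2 -1.461 (0.647, -0.814), Lgals3 -1.355 (1.132, -0.223), Guca2b -6.141 (5.478, -0.663), Hsd3b1 -4.969 (4.765, -0.203), Cyp11a1 -4.536 (4.497, -0.038), Malat1 4.111 (-3.592, 0.519), Resf1 3.395 (-2.732, 0.663), Taok1 2.812 (-2.47, 0.342) and Akr1cl -4.313 (4.4, 0.087). In most of them the change in Pten+/-;Mlh1-/- mice is small beside that in Pten+/- mice.

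Camera called 11 lists for the interaction, and all were lost with an estimated correlation (adjusted p = 0.068 to 0.6). Given as the median interaction with the median change in each genotype, they are sterol and fatty acid synthesis -0.937 (0.686, -0.375), glycolysis and hypoxia -1.207 (0.915, -0.176), p53 targets -0.451 (0.384, -0.124), early response and heat shock -0.781 (0.516, -0.207), oxidative phosphorylation -0.339 (0.274, -0.03), epithelium -0.716 (0.623, -0.089), endometrial stroma 0.682 (-0.681, 0.008), smooth muscle 0.63 (-0.46, 0.142), skeletal muscle 1.086 (-0.757, 0.352), neutrophil -1.541 (1.125, -0.277) and ovary -0.963 (1.446, 0.054). The sterol list was itself called lower by camera in Pten+/-;Mlh1-/- mice (-0.375, adjusted p = 0.62 with an estimated correlation).

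Besides Cyp11a1 and Hsd3b1, the aldo-keto reductase genes Akr1c18 and Akr1cl were high on both Pten+/- invasive arrays. Akr1c18 was at 1931 and 2376 (at most 284 elsewhere) and Akr1cl at 2508 and 6520 (at most 451). Ovarian tissue in the sampled segments is a candidate explanation that the test could not settle, since the 4 other ovary genes had a median of 0.80 where 1 was asked for. Inha (633 and 2194, at most 444 elsewhere) and Star (346 and 356, at most 280) were above every other array, and Nr5a1 (139 and 370, at most 178) only on array 2. Inhba, the remaining one, did not differ in its mean (-0.02) and lay at 36.5 and 217, under the highest other array (303). Cyp11a1, Hsd3b1, Akr1c18 and Akr1cl differed by a median of -0.03 between the targets within Pten+/-;Mlh1-/- mice. This argues against an effect of the target of 250 common to all arrays. A batch effect particular to the Pten+/- invasive arrays could not be tested, since all Pten+/- hyperplasia arrays had the target 500. Whether the tumour cells themselves make steroids was not tested.

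The many changes in Pten+/- invasive carcinoma coincide with a change of scaling target. The fold changes correlated at r = -0.05 with the difference between targets in Pten+/-;Mlh1-/- hyperplasia, where other splits gave 0.053 and 0.080. They thus did not follow the target in those 4 arrays. A batch effect particular to the Pten+/- arrays cannot be excluded, since their lesions and targets coincide. Degraded RNA stays open, since the 3' to 5' ratios of Gapdh and Actb differed by 0.09 on the log2 scale in its direction but overlapped those of hyperplasia. With the smooth muscle list mean as a covariate 730 genes passed, 548 of them among the 888, so muscle content by itself leaves most calls in place. Other differences of tissue content or of stage between these 2 mice and the others were not tested.

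Hyperplasia against wild type depended on the wild-type array left out (8, 12 or 715 genes). A low-estrogen stage of wild-type array 30 could contribute, since 14 estrogen-list genes not looked at before were lower on it by a median of -0.94 (10 of 14 lower, Lcn2 at -6.54). Less epithelium on that array is an alternative that the data cannot tell apart from it, with the epithelium list lower by -0.86. The uterine gland list, also epithelial, was higher on it (1.814, against -1.041 and -0.773 on arrays 15 and 42), as was the progesterone list (0.515, against -0.272 and -0.243), so a loss of all epithelium alike is not what the lists show. The array whose absence raised the count most was 42, and the cause of that was not tested.

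Chance as the source of the counts was tested by regrouping. Fewer than 5 in 100 splits gave as many genes for hyperplasia over both genotypes (68 genes, 2 of 100 splits with as many counting the real one, highest other 98), for Pten+/-;Mlh1-/- hyperplasia (78 genes, 1 of 35, highest other 12) and for invasive carcinoma against wild type (724 genes, 1 of 100, highest other 334). Chance is less likely for these counts but not excluded. A share of 1 of 35 is the lowest possible there, and the shares were not corrected for the number of comparisons. Chance remains a possible source for Pten+/- hyperplasia (7 genes, 5 of 35, highest other 232) and Mlh1 loss in hyperplasia (1 gene, 3 of 35, highest other 125). Invasive carcinoma against hyperplasia gave 7 of 100 (74 genes, highest other 390) and Mlh1 loss over both lesions 5 of 100 (291 genes, highest other 763). Some splits there, such as those with 390 and 763 genes, keep the Pten+/- invasive arrays together and so keep a real difference. The regrouping therefore cannot tell for these comparisons. The comparisons that set groups of 2 arrays apart (888, 0 and 743 genes, and 273 for the interaction) were not regrouped, since a group held fewer than 3 arrays.

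Splits that call several times the real count point to a structure of the samples. The split with 390 genes kept the Pten+/- groups and set Pten+/-;Mlh1-/- hyperplasia arrays 7 and 8, scaled to 500, against 4 arrays scaled to 250, opposite to the Pten+/- arrays, so an effect of the target would cancel in it. The split with 763 genes exchanged the invasive groups and paired hyperplasia arrays 1, 3, 5 and 6 against 2, 4, 7 and 8. The split with 232 genes put hyperplasia arrays 2 and 4 with wild-type array 15, and the split with 125 set 2, 4, 5 and 8 against 1, 3, 6 and 7. That last division also shows in the arrays themselves, seen after the result. The SD of log2 differences was 0.383 for arrays 1 and 3, 0.313 for 2 and 4, 0.378 for 5 and 8 and 0.354 for 6 and 7, against 0.481 to 0.581 for the other pairs within a genotype. On the first principal component 2, 4, 5 and 8 lay at 10.4 to 12.1 and the others at -22.4 to -2.2. The erythrocyte list mean was 0.801, 1.234, 1.005 and 1.495 on arrays 1, 3, 6 and 7 and -0.007 to 0.222 on the other 4, and the T and NK cell, endothelium, progesterone and ribosomal lists were also higher and the glycolysis and matrix lists lower on all of the former. What causes the division was not tested.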

How the results depend on the processing

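The scaling target as a covariate, the fits within a target and those without a pair of invasive arrays were chosen after seeing the data. Alternatives were run for all counts, all list calls, the named genes past the threshold and the uncalled genes named in the text, which were chosen after their values were seen. The cause of a change was not tested unless stated. The number of arrays limits every count, and leaving out 1 array changed most of them. Where an invasive array was left out, its group held a lone array, assumed to vary like the other groups.

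Leaving out each array in turn gave 8 to 715 genes for hyperplasia against wild type over both genotypes (68 with all arrays), 2 to 404 for Pten+/- (7) and 18 to 529 for Pten+/-;Mlh1-/- hyperplasia (78). It gave 0 to 71 for invasive carcinoma against hyperplasia over both genotypes (74), 145 to 800 for Pten+/- (888), 0 in each case for Pten+/-;Mlh1-/- (0) and 154 to 1162 for invasive carcinoma against wild type (724). For Mlh1 loss it gave 0 to 11 in hyperplasia (1), 66 to 366 in invasive carcinoma (743), 0 to 402 over both lesions (291) and 10 to 262 for the interaction (273). Over all single genes and arrays left out, a call was lost 575 times and gained 18 times, and in the other 1329 cases a gene stayed past or not past the threshold.

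Offset, filter and normalization had smaller effects. With an offset of 10, Mlh1 loss in hyperplasia gave 0 genes. With an offset of 200, Pten+/- hyperplasia gave 1. Without the filter Mlh1 loss in hyperplasia gave 0 and the interaction 154, and with a filter at 300 Pten+/-;Mlh1-/- hyperplasia gave 51. With every probe set tested Pten+/- hyperplasia gave 12. Quantile normalization left every count within 1.5 times, with 12 gene calls lost and 1 gained, and 222 genes that stayed past or not past the threshold.

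Values as deposited mix the targets 250 and 500, which by construction shifts the invasive arrays down. Invasive carcinoma against hyperplasia gave 6606 genes (6593 lower, median shift -0.65), in Pten+/- mice 5740 (5705 lower, -0.873), and against wild type 6612 (6573 lower, -0.841). Pten+/-;Mlh1-/- hyperplasia gave 255, Mlh1 loss 31 in hyperplasia, 32 in invasive carcinoma and 26 over both lesions, and the interaction 60. Signs reversed for Mvd (-0.052) over both genotypes. In Pten+/- invasive carcinoma they reversed for Tpi1 -0.018, Zfp36 -0.161, Dnajb1 -0.33, Ndufv1 -0.21, Uqcrc1 -0.335, Atp5a1 -0.421, Cyc1 -0.303 and Star -0.276. Against wild type they reversed for Nsdhl -0.225, Ldha -0.297, Slc2a1 -0.229, Msr1 -0.039 and Fcgr1 -0.031.

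With only the groups compared, the counts were 24 for hyperplasia over both genotypes, 0 for Pten+/- and 20 for Pten+/-;Mlh1-/- hyperplasia, 182 for invasive carcinoma against hyperplasia, 3 in Pten+/-;Mlh1-/- mice, 271 against wild type, 1617 for Mlh1 loss in invasive carcinoma, 571 over both lesions and 444 for the interaction. The 3 in Pten+/-;Mlh1-/- mice, named after their values were seen, were Serpina1c (4.43), 2210407C18Rik (2.988) and Ifi202b (-3.605). For Mlh1 loss in hyperplasia the 1 gene was Guca2b (2.936, adjusted p = 0.027) in place of Igk (adjusted p = 0.2). With array weights they were 7, 2 and 29 for hyperplasia (both genotypes, Pten+/-, Pten+/-;Mlh1-/-), 397 for invasive carcinoma against hyperplasia, 32 in Pten+/-;Mlh1-/- mice, 284 against wild type, 10, 2008 and 1202 for Mlh1 loss in hyperplasia, in invasive carcinoma and in both, and 791 for the interaction.

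With the smooth muscle list as a covariate, each of the 3 hyperplasia comparisons gave 1 gene, invasive carcinoma against wild type 22 and the interaction 178. Camera's direction turned for the interferon list in Pten+/-;Mlh1-/- hyperplasia, whose median stayed above 0 (0.053, against 0.353 without the covariate, adjusted p = 0.91). The median of the smooth muscle list in the interaction changed sign (-0.098, adjusted p = 0.93). The covariate removes the part of a difference that follows the muscle list within groups, and it can widen errors. In hyperplasia over both genotypes S100a8 went from 3.66 (SE 0.449) to 3.37 (SE 0.615). Ogn went from -1.03 (SE 0.156) to -0.95 (SE 0.213). Cxcl5 went from 2.97 (SE 0.441) to 2.23 (SE 0.536), and Myl9, a member of the list, from -0.84 (SE 0.154) to -0.46 (SE 0.147). A lost call can thus come from a wider error as well as from a smaller change.

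With the number in the label as a replicate block, Pten+/- invasive carcinoma gave 1 gene. Whether the Pten+/- arrays that share a number come from the same mouse is not known. Their correlations (r = 0.114 and 0.031) cannot decide it, since the deviations of the invasive pair mirror each other. The other values (r = 0.011 and -0.022) pair arrays of different genotypes, which are different mice. The block also uses up degrees of freedom.

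With the scaling target as a covariate, hyperplasia over both genotypes gave 34 genes and Pten+/-;Mlh1-/- hyperplasia 4. Invasive carcinoma against hyperplasia gave 0, Pten+/- invasive carcinoma 80, invasive carcinoma against wild type 1, and Mlh1 loss 0 in hyperplasia and 36 over both lesions. Within the arrays scaled to 500, hyperplasia gave 1 (both genotypes), 1 (Pten+/-) and 3 (Pten+/-;Mlh1-/-), and Mlh1 loss in hyperplasia 1, which was Cldn4 (1.732, adjusted p = 0.048) in place of Igk (adjusted p = 0.57). Within those scaled to 250, Pten+/-;Mlh1-/- invasive carcinoma gave 2 and Mlh1 loss in invasive carcinoma 1154.

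Without the Pten+/- invasive arrays, invasive carcinoma against hyperplasia gave 0 genes and against wild type 11. Signs reversed against hyperplasia for Cyp11a1 -0.038, Hsd3b1 -0.203 and the lists sterol -0.375, glycolysis -0.176, epithelium -0.089, stroma 0.008 and neutrophil -0.277, and against wild type for Slc2a1 -0.058 and Hsd3b1 -0.228. Without the Pten+/-;Mlh1-/- invasive arrays the counts were 705 and 1485. The counts over both genotypes rest largely on the Pten+/- arrays in this sense, although they also fell without either Pten+/-;Mlh1-/- invasive array. Of the list calls, 6 held without the Pten+/- invasive arrays, so not every result over both genotypes rests on them.

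Of 110 list calls, 1 held with an estimated correlation and 109 did not. In the region test near Mlh1, a window of 5 Mb gave 28.2% of genes with p under 0.05.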

Other observations

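No test in this part was chosen after its result was seen, but the bound for excluding flanking DNA was made stricter afterwards, to ask for a share below that of 95% of random sets.

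Neutrophils in the tissue are a hypothesis for the rise of S100a8 and S100a9 in hyperplasia. The 8 measured genes of the list other than S100a8, S100a9 and Csf3r had a median of 0.62 on the log2 scale, above the 0.5 asked for. The result goes with the hypothesis, but the 8 include Il1b, itself among the called genes (1.57), and come from the same arrays. The test is therefore not separate from the rise it is meant to explain. The list mixes levels, since Ltf, the most abundant member (mean signal 16440), is also in the estrogen list and Mmp9 in the matrix and invasion list, the only 2 shared with other lists. S100a9 and S100a8 had means of 1632 and 1622, and Mpo, made in the bone marrow, was not higher (-0.25). No cell was counted, and epithelial cells can make S100 proteins too.

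DNA that travelled with the Mlh1 knockout allele is a hypothesis for some changes with Mlh1 loss. Within 10 Mb of Mlh1, 25% of 124 genes had p under 0.05, against 20% of all genes (permutation p = 0.098), so the test could not tell. With 20 Mb the share was 23% (permutation p = 0.17), and with 5 Mb 28.2% (permutation p = 0.041). The genes near Mlh1 past the adjusted threshold were Ctnnb1 (0.63), Gnai2 (-0.54), Ngp (-0.97), Parp3 (-1.50) and Uqcrc1 (-0.44). Ngp and Uqcrc1 fell in invasive carcinoma (-1.78 and -0.83). They belong to the neutrophil and oxidative phosphorylation lists, which camera called lower there, calls that were lost with an estimated correlation (adjusted p = 0.16 and adjusted p = 0.73). Near Pten, 15.8% of 76 genes had p under 0.05 in hyperplasia, against 16.1% of all genes (permutation p = 0.58). A share at the level of random sets shows no excess, but over 76 genes it cannot exclude that flanking DNA changes some of them, so that stays open too.

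Lists that passed in no comparison are given by their smallest camera adjusted p. They were T and NK cells 0.13, adipocyte 0.13, erythrocyte 0.094, estrogen-responsive 0.4, matrix and invasion 0.21, mesothelium 0.09, progesterone-responsive 0.21, squamous epithelium 0.061, uterine gland 0.63 and Wnt targets 0.12.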
